A study of Drosophila melanogaster with 4 samples.

How the data were processed

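KDM4A ChIP-seq with the antibody Q2541 was carried out on 2 samples of head nuclei from adult Oregon-R flies, with 1 input sample for each. Per the labels' protocols, heads were collected with sieves, the tissue was homogenized and fixed with formaldehyde, chromatin was sheared by sonication, and each input served for the region list of the ChIP with the same replicate number. Bowtie 0.12.7 is named in the submitters' processing notes. Per the file headers the coordinates are of FlyBase release 5, with 14 reference sequences: the arms 2L, 2R, 3L, 3R and X, chromosome 4, 6 heterochromatic scaffolds, and the unplaced collections U and Uextra. The caller, its threshold and its filters are not given in the sources used here, nor is it stated whether the replicates were pooled before the replicate-set list was called.

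Each deposited list gives regions of significant enrichment with a position and 1 score, which the authors assigned. The scale of the deposited score is not stated. All 8653 enriched regions of the replicate-set list score above 0 and its single region of depletion, which was left out of the analysis, scores just below 0, so scores were compared by rank, median and difference and not as folds. The exception is a planned correlation of log2 scores, which is given beside that of the scores as deposited. No regions overlapped within a list. The shortest region was 1301 bp in both replicate lists and 1001 bp in the replicate-set list. The lists hold no read counts, so the depth behind each region is unknown, and no interval for a region's score is given. Intervals given for shares of regions are 95% Wilson intervals and cover the counting of regions only.

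From these lists the following was computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Reproducible regions are regions of the replicate-set list that overlap a region of each replicate list by at least 1 bp. The replicate-set list is not independent of the replicates. Overlap between the replicates was tested against 1000 random placements that kept the number and widths of regions per chromosome and let none overlap. For overlap of at least 50% of both regions, 100 placements were drawn. Coverage was measured in 100 kb windows (a last window under 50% of that size was dropped). Windows of X, chromosome 4, the heterochromatic scaffolds together and U were each compared with those of 2L, 2R, 3L and 3R by permuting windows 100000 times, two-sided, with Benjamini-Hochberg adjustment over the 4 classes. The 2 Mb of each assembled arm toward its centromere (the high-coordinate end of 2L, 3L and X and the low-coordinate end of 2R and 3R), called next to the centromere here, was compared with the rest of each arm by circular shifts of its windows. The separate heterochromatic scaffolds are not part of it. The shifts were all taken for each arm, with adjustment over the 5 arms, and 100000 random combinations were drawn for the arms together. Medians of width and score were compared by permutation with 100000 resamples. The shift of X scores between the replicates and the share of X among the highest-scored regions were each given a 95% interval from 2000 bootstraps over blocks of 1 Mb. No test across the 2 replicates was run, since an exact sign-flip test of 2 values cannot go below p = 0.5, so every p describes positions or regions within these lists.

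The regions named were chosen by a rule fixed before the data were examined: the 10 highest-scored and the 5 widest reproducible regions, the 3 highest-scored on X, on chromosome 4, on the heterochromatic scaffolds and on U, and the 3 highest-scored regions of each replicate that the other did not overlap. The tests, the groups and most alternatives were also fixed before the data were examined. Alternatives were other sets of regions, the higher-scored 50% of the regions, each replicate's list alone, stricter overlap, other window sizes, and other lengths of centromere-proximal sequence. A planned count of regions at promoters and a planned test of 16 gene lists were not run, because the gene table at hand is of release 6 and positions cannot be moved between releases here.

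The procedures were tested on simulated lists with the 6656 region widths of replicate 1. Of 20 randomly placed lists, 1 passed the overlap test at 0.05. For X against the arms, with X windows drawn at random from the arm windows, 1 of 20 simulations without an effect and 20 of 20 with coverage raised 1.5 times passed. For the centromere-proximal test, 1 of 20 lists without an effect and 20 of 20 with proximal coverage multiplied by 0.5 passed. All simulated regions were placed at random, so their windows lack the clustering of the real ones. The simulations therefore do not give the rate of false calls with clustered windows, nor the power for differences smaller than those planted.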

Results

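KDM4A (also named JMJD2A) is a histone lysine demethylase that removes methyl groups from histone H3 and is known to bind the heterochromatin protein HP1a. Its binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in head nuclei of mixed adult flies of the wild-type strain Oregon-R. The series held 2 KDM4A ChIP samples, replicates 1 and 2, and 2 input samples of sonicated chromatin, one for each ChIP. The values were the authors' lists of enriched regions, 1 for each ChIP sample and 1 for the replicate set, with 1 score per region. Read depth was unknown, and the inputs entered only through the authors' calls against them. No label said that the 2 replicates came from separate fly collections, so their spread may be technical. Positions are on FlyBase release 5 (counted from 1), and no annotation of that release was used here, so regions are named by position and not by gene.

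KDM4A-enriched regions lay on every arm, on chromosome 4, on each heterochromatic scaffold and in U, the collection of unplaced sequence. On the large arms and X the median gap between neighbouring regions was 4811 bp in replicate 1 and 4413 bp in replicate 2. Replicate 1 held 6656 regions over 20.3 Mb and replicate 2 held 7382 regions over 21.9 Mb, a mean of 7019 ± 513 regions (SD, n = 2) and 21.1 ± 1.14 Mb (SD, n = 2). The median region was 2415 bp wide in replicate 1 and 2178 bp wide in replicate 2. The list of the replicate set held 8653 regions over 26.4 Mb. Of these, 4534 regions (52.4%), over 19.9 Mb, overlapped a region in each replicate list by at least 1 bp and are called reproducible regions below.

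The highest score among the reproducible regions, 3.72, belonged to a region of 2598 bp on X at 5417240 to 5419837, which scored 3.95 in replicate 1 and 3.46 in replicate 2. Next came a broad region on 2L at 2190990 to 2204485, with a score of 3.27, and a region on the heterochromatic scaffold 3LHet at 1394407 to 1398970, with a score of 3.25. The region on 2R at 2547101 to 2552504 scored 3.24, and a second X region at 17041049 to 17044476 scored 3.23. The other five of the top 10 lay on 2L at 4809093 to 4813578 (score 3.14), on 3L at 9433210 to 9437113 (score 3.09), on 3R at 13428466 to 13433564 (score 3.00), on X at 5630836 to 5633289 (score 2.98) and on 2L at 11984799 to 12013547 (score 2.91). All of the top 10 scored at least 2.67 in each replicate. The widest reproducible regions were 33251 bp on 3R at 7032703 to 7065953, 28947 bp on 2L at 19029470 to 19058416, 28749 bp on 2L at 11984799 to 12013547, 28435 bp on 3R at 5380053 to 5408487 and 28286 bp on 2L at 4440066 to 4468351. The 2L region at 11984799 was therefore among both the highest scored and the widest.

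The first comparison asked how far the replicates marked the same sequence. Of the 6656 regions of replicate 1, 5142 (77.3%, 95% Wilson interval 76.2 to 78.2%) overlapped a region of replicate 2, against 30.1% when the regions were placed at random on their own chromosomes (one-sided permutation test with 1000 placements, p = 0.001, the smallest they can give). In the other direction 5097 of 7382 regions (69.0%, interval 68.0 to 70.1%) overlapped, against 27.5% by chance (the same permutation test, p = 0.001). By chromosome class, of the replicate 1 regions 80.8% overlapped on the autosomal arms, 67.6% on X, 54.2% on chromosome 4, 60.6% on the heterochromatic scaffolds and 50.0% on U. Of the replicate 2 regions the shares were 68.9% on the arms, 81.6% on X, 59.5% on chromosome 4, 24.8% on the scaffolds (95% Wilson interval 19.4 to 31.0%) and 34.4% on U (interval 25.4 to 44.7%), and these differences between classes were not tested. Chance was not computed by class, and it is lower where less sequence is covered, as on the scaffolds and U. The shares therefore do not rank the classes by their excess over chance. The replicates shared 14.9 Mb, which was 54.5% of the sequence covered by either, against 9.25% by chance. Intervals and permutation tests here treat regions and windows as independent, which neighbouring ones are not, and none of them is a test across samples.

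Overlap was highest among the highest-scored regions. With the regions of replicate 1 split by score into 4 equal groups, from lowest to highest, 58.2%, 62.9%, 89.8% and 98.1% overlapped. In replicate 2 the same groups gave 62.0%, 47.4%, 71.0% and 95.8%, so that the second group lay below the lowest. Chance was not computed for the score groups. Wider regions overlap more readily by chance, and the shares were not corrected for width. Across the 3581 regions that overlapped one to one, the scores of both replicates correlated with a Spearman rho of 0.73 and a Pearson r of 0.77 on the scale as given. On the log2 of the score, the scale planned before it was known that scores may already be logarithmic, r was 0.66. The covered share of 119 windows of 1 Mb on the large arms and X correlated with a Spearman rho of 0.85. Regions and windows are not independent replicates, so no p is given. Regions of 1 replicate alone could still score high. The highest in replicate 1 were on 2RHet at 2283254 to 2285750 (score 3.29), U at 3915881 to 3917328 (score 2.85) and 3L at 23663325 to 23665395 (score 2.69). The 3 highest in replicate 2 were all on U, at 9226932 to 9228856 (score 3.53), 2753736 to 2755245 (score 3.47) and 6224437 to 6225833 (score 3.27).

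**Figure D1:**
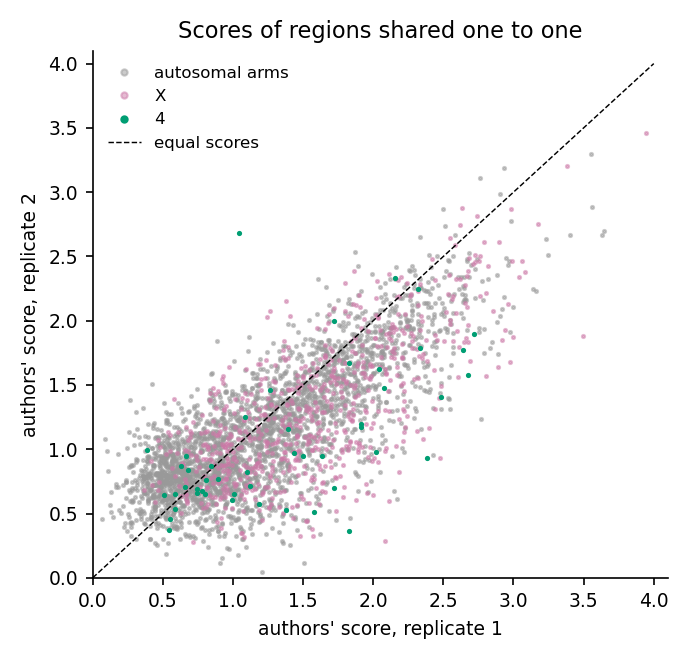
Authors' score of each region shared one to one by replicate 1 (x axis) and replicate 2 (y axis), 1 point per region, coloured by chromosome class; the dashed line marks equal scores. Scores rise together (Spearman rho 0.73 over 3581 regions, of which a few on the scaffolds are not drawn), and most high-scored regions lie below the line, with higher scores in replicate 1.

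Regions of the replicate-set list held by both replicates were wider and higher scored than the other 4119. Their median width was 3375 bp against 1435 bp, and their median score was 1.07 against 0.47 (two-sided permutation tests with 100000 resamples, p = 1e-05 for each, the smallest they can give). The split is not independent of these measures, because strong and wide regions are the likelier to be called in each replicate.

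The second comparison set the chromosomes against each other, since KDM4A binds a heterochromatin protein. The 4 large autosomal arms were covered over 17.6 ± 1.57% of their length (SD, n = 2), highest on 2R with 20.5 ± 2.54% and lowest on 3L with 16.1 ± 0.783%. The small chromosome 4, which is rich in heterochromatin but carries expressed genes, was covered over 21.4 ± 2.51% (SD, n = 2), and X over 15.1 ± 2.28% (SD, n = 2). The 6 heterochromatic scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) were covered over 3.41 ± 1.57% and U over 1.46 ± 0.231% (SD, n = 2 for each). Within the scaffolds XHet was covered over 8.26 ± 0.900% and YHet over 1.23 ± 0.309% (SD, n = 2).

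Reproducible regions covered the heterochromatic scaffolds at 0.109 times and U at 0.0476 times the share of the autosomal arms in 100 kb windows (two-sided permutation tests with 100000 resamples, Benjamini-Hochberg over 4 classes, adjusted p = 2e-05 for each). By circular shifts of the windows, which keep neighbours together, the adjusted p was 0.0019 for each. Each replicate's own list gave the same direction, with ratios for the scaffolds of 0.138 in replicate 1 and 0.240 in replicate 2, and for U of 0.0791 and 0.0872. The scaffolds held 71 regions in replicate 1 and 210 in replicate 2. How much of the scaffolds reads could be placed on was not measured, and no list held a region on Uextra, so these shares are of all sequence and not of readable sequence.

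For chromosome 4 the ratio to the autosomal arms was 1.05 (adjusted p = 0.85, same permutation test), with 1.44 in replicate 1 (adjusted p = 0.051, permutation test) and 1.05 in replicate 2 (adjusted p = 0.80, permutation test). No difference of chromosome 4 from the arms passed the test, over only 14 windows. For X the ratio was 0.875 (adjusted p = 0.059, permutation test). It was 1.01 in replicate 1 (adjusted p = 0.85, permutation test) and 0.718 in replicate 2 (adjusted p = 1e-05, permutation test), so a lower coverage of X rested on replicate 2 alone. With circular shifts of the windows, which keep neighbours together, the X ratio of replicate 2 did not pass (adjusted p = 0.056, permutation by shifts). By the same shifts the chromosome 4 ratio of replicate 1 had an adjusted p of 0.16.

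**Figure D2:**
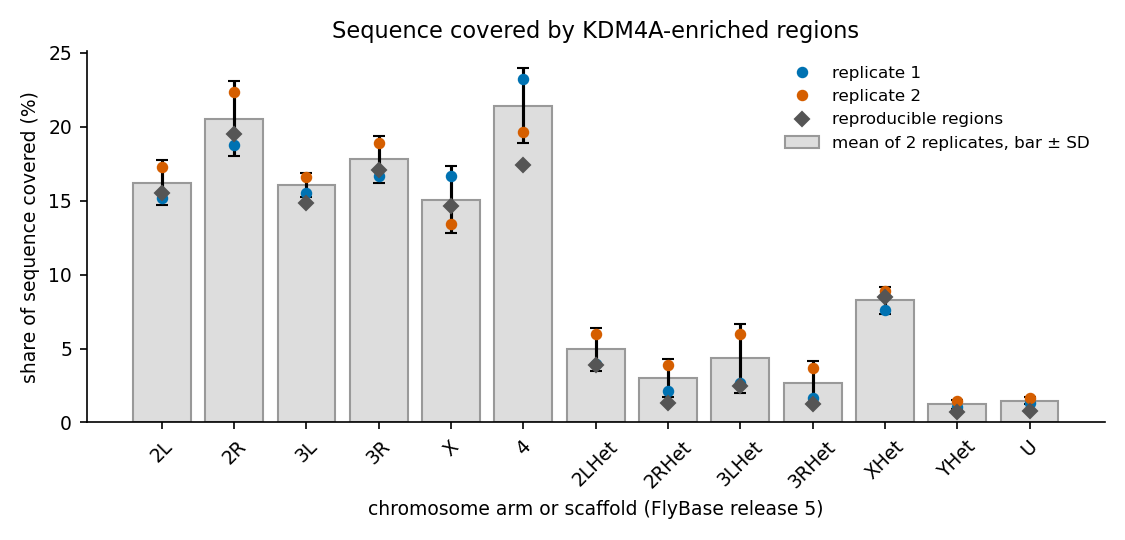
Share of each chromosome arm or scaffold covered by enriched regions, in percent of its length; grey bars show the mean of the 2 replicates with the SD, circles the replicates and diamonds the reproducible regions. Arms and chromosome 4 lie between 13.5 and 23.2% in both replicates, and every heterochromatic scaffold and U lies below 9%.

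The highest-scored reproducible regions of chromosome 4 lay at 977949 to 981851 (score 2.44), 225595 to 231956 (score 2.26) and 1315475 to 1317842 (score 2.25). After the 3LHet region named above, the scaffolds' highest were on 2RHet at 3196180 to 3200347 (score 2.40) and on YHet at 304200 to 306574 (score 2.24). On U they lay at 9288013 to 9290359 (score 2.86), 9094073 to 9096795 (score 2.66) and 7530810 to 7533145 (score 2.01).

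Over the assembled arms together, the centromere-proximal ends were less covered than the rest. The centromere-proximal 2 Mb of 2L, 2R, 3L, 3R and X had a mean covered share of 11.2% against 16.8% for the remainder, a ratio of 0.667 (two-sided test by circular shifts of the 100 kb windows within arms, permutation p = 0.0022). The arms differed. On 3L the proximal share was 3.67% against 15.9% (adjusted p = 0.041, exact over all shifts) and on X it was 6.72% against 15.4% (adjusted p = 0.045, exact over all shifts). It was 12.4% against 20.3% on 2R (adjusted p = 0.063, exact) and 10.96% against 15.96% on 2L (adjusted p = 0.33, exact). On 3R the proximal 2 Mb had the higher share, 22.4% against 16.7%, which did not pass the test (adjusted p = 0.20, exact). The calls of the single arms were less stable than the combined one: in the list of replicate 2 neither passed (adjusted p = 0.055 for each, exact), and the 3L share there was 8.77% against 17.3%, a ratio of 0.506 in place of 0.231. With 1 Mb of proximal sequence neither passed either (adjusted p = 0.06 on 3L and 0.11 on X, exact), and X also lost its call in the higher-scored 50% of regions (adjusted p = 0.12, exact) and with 4 Mb (adjusted p = 0.33, exact). Each replicate's own list gave the same combined direction, with a ratio of 0.664 in replicate 1 (permutation p = 0.00077) and 0.750 in replicate 2 (permutation p = 0.01). How much of these arm ends reads could be placed on was not measured.

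**Figure D3:**
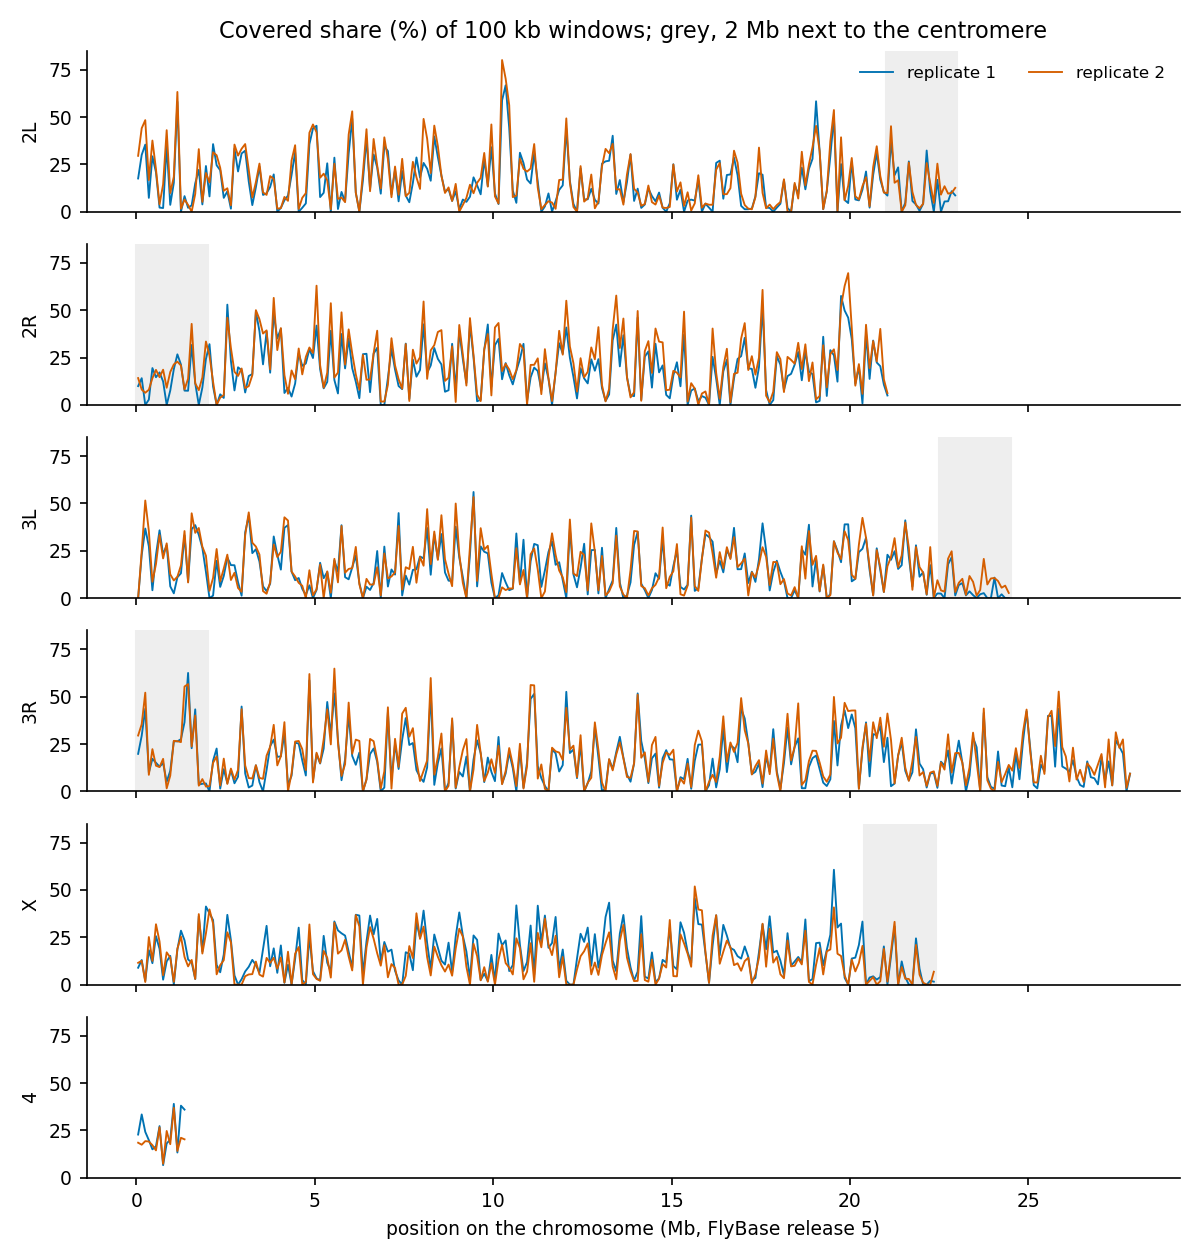
Covered share, in percent, of 100 kb windows along 2L, 2R, 3L, 3R, X and 4 (position in Mb) in replicate 1 (blue) and replicate 2 (orange); grey marks the 2 Mb next to the centromere. The replicates follow each other (Spearman rho 0.85 over 1 Mb windows), coverage is low at the centromere end of 3L and X, and on much of X replicate 1 lies above replicate 2.

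Called regions on X had higher scores than called regions on the autosomal arms. Sequence that was not called has no score, so this does not compare enrichment of X as a whole with that of the arms. Whether the lowest score that could be called differed between X and the arms was not tested. Among reproducible regions the median score was 1.28 on X (811 regions, quartiles 0.896 and 1.67) and 1.02 on the arms (3594 regions, quartiles 0.638 and 1.43), a difference of 0.26 (two-sided permutation test of medians, adjusted p = 4e-05). The difference was 0.23 in replicate 1 and 0.20 in replicate 2 (adjusted p = 4e-05 for each, permutation tests). These tests, like the others of this paragraph, treat neighbouring regions as independent. No test that keeps neighbours together was run for scores. The median width did not differ detectably, with 3310 bp on X and 3408 bp on the arms (adjusted p = 0.38, permutation test). Chromosome 4 had a median score of 1.05, which did not pass against the arms (adjusted p = 0.81, permutation test), but in the list of replicate 2 its median was 0.77 against 0.93 (adjusted p = 0.00073, permutation test). For U the median score was 1.30 over 31 reproducible regions (adjusted p = 0.078, permutation test). The U difference passed in each replicate's own list, at 0.44 in replicate 1 (adjusted p = 0.00058) and 0.26 in replicate 2 (adjusted p = 0.00012), both by permutation tests. The heterochromatic scaffolds had a median score of 1.19 over 41 reproducible regions (adjusted p = 0.20, permutation test), and passed only in the list of replicate 1, where their median exceeded that of the arms by 0.27 (adjusted p = 0.019, permutation test).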

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

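One alternative null for the chromosome test and one for the overlap test were chosen after seeing the data, and the rest were planned. Overlap of the replicates, the low coverage of the heterochromatic scaffolds and U, the low coverage next to the centromere over all arms together, the higher score on X and the larger width and score of regions held by both replicates kept their direction and their side of the threshold under every alternative run for them. None of those run for the X score kept neighbouring regions together. The overlap of replicate 1 ranged from 58.1% (at least 50% of both regions) to 80.0% (higher-scored 50% of each list). Chance was 8.70% in the first setting, from 100 placements, and 20.8% in the second, against 30.1% in the main test. The centromere ratio ranged from 0.515 (1 Mb) to 0.843 (4 Mb, permutation p = 0.041). Keeping the higher-scored 50% left 4328 regions of the replicate set, 3328 regions over 13.1 Mb of replicate 1 and 3691 regions over 14.5 Mb of replicate 2, by construction. Pearson's r of the scores was 0.77 on the scale as given. The ratio of X to the autosomal arms was 0.984 over all regions of the replicate-set list (permutation test, adjusted p = 0.78) and 0.875 with circular shifts (adjusted p = 0.21), and 0.841 where each replicate covered at least 50% of the region and 0.875 in 50 kb windows, the last 2 then past the threshold (adjusted p = 0.015 and 0.03). It turned to 1.06 in the higher-scored 50% and, leaving out 1 replicate, ran from 0.718 (without replicate 1) to 1.01 (without replicate 2). For chromosome 4 the ratio was 1.37 over all regions of the replicate-set list (permutation test, adjusted p = 0.082), and it turned to 0.886 with at least 50% covered and to 0.927 in the higher-scored 50%, neither past the threshold. The median width of chromosome 4 minus that of the arms turned from 326 bp to -349 bp with at least 50% covered, and the score difference of U passed at 0.35 with that setting. Leaving out a replicate, the width differences from the arms ran from -71 to 45 bp on X, from -159 to -109 bp on chromosome 4, from -526 to 44 bp on the heterochromatic scaffolds and from -566 to -444 bp on U. Of these, the list of replicate 2 alone turned the scaffolds from 417 bp wider than the arms to narrower and past the threshold (adjusted p = 0.00024), and made U pass (adjusted p = 0.007, permutation). The score differences ran from -0.17 to 0.0035 on chromosome 4, from 0.027 to 0.27 on the scaffolds and from 0.26 to 0.44 on U. The cause of these changes was not tested. Both planned results that need gene positions were not run under any setting. No paired analysis was possible because only the KDM4A ChIP samples had values, so no second group could be matched to them by replicate number. The depth behind the lists is unknown.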

Other observations

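Both tests of X in this part were chosen after the difference on X was seen but set out before their own results, and the other tests were chosen after their results were seen. Coverage by reproducible regions varied widely along the large arms and X. Over 119 windows of 1 Mb the median covered share was 16.0%, from 2.08 to 31.1%. The densest windows were 2R from 3000001 to 4000000 (31.1%, 57 regions) and 2L from 10000001 to 11000000 (30.9%, 55 regions), followed by 3R from 5000001 to 6000000 (29.5%, 52 regions). By reproducible regions the sparsest were the last 2 windows of 3L next to the centromere, from 23000001 to 24000000 (2.08%) and from 24000001 to 24543557 (2.35%). Their shares were 2.63% and 3.20% in replicate 1 but 8.44% and 7.35% in replicate 2, where the 2L windows named below were sparser. A pair of windows far from a centromere were sparse in both replicates. On 2L from 17000001 to 18000000 the share was 5.87% in replicate 1 and 6.84% in replicate 2, and on 2L from 14000001 to 15000000 it was 6.07% and 5.51%.

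The replicates differed on X. From replicate 1 to replicate 2 the regions on X fell from 1305 to 1126 while those on the 4 autosomal arms rose from 5111 to 5845, and the covered share changed in opposite directions (16.7 to 13.5% of its length on X, 16.5 to 18.7% on the arms, with a rise on each of 2L, 2R, 3L and 3R). A different stringency that kept the order of the scores would leave X the same share of equal numbers of the highest-scored regions. Among the top 3208 regions of X and the arms in each list, X held 24.8% in replicate 1 and 22.5% in replicate 2, a difference of -2.21 percentage points (95% block bootstrap interval -3.25 to -0.896). That argues against such a difference of stringency alone as the whole cause. The gap over the whole lists was wider at -4.19 points, outside that interval, so stringency may account for part of it. The comparison cannot decide on depth, because depth can also reorder scores. X held less of the whole lists (20.3% in replicate 1, 16.2% in replicate 2) than of the top regions, so reordering alone could move its share. The interval covers positions only, and no effect of depth was tested. A lower score of X sequence as a whole in replicate 2 may account for part of the difference on X: given the replicate 1 score, the median score of shared X regions minus that of the arms was -0.058 (95% block bootstrap interval -0.101 to -0.0041, 698 X and 2777 arm regions). That offset is small but depends on the linear fit to the arms (slope 0.625), and only regions called in both replicates entered it. Without the fit, the median score of these regions went from 1.51 in replicate 1 to 1.20 in replicate 2 on X. On the arms it went from 1.13 to 1.05. Coverage of chromosome 4 also fell, from 23.2 to 19.7% of its length, although its regions went from 107 to 111. The heterochromatic scaffolds rose on both measures, as the arms did, from 71 to 210 regions and from 2.30 to 4.52% of their length. A different mix of males and females between the 2 ChIPs or inputs stays open and untested, because no label gives the mix.

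The replicate-set list held 1593 regions (18.4%) that overlapped no region of either replicate, and lacked 1315 regions (17.8%) of replicate 2 but only 201 (3.02%) of replicate 1. A shorter minimum width in the replicate-set list may account for many of the 1593: 64.6% of them, 1029 regions, were shorter than the shortest replicate region of 1301 bp, against 23.3% of regions overlapped by 1 replicate. The remaining 564 were not. Weak enrichment that only joint data reach stays open. The median score of these regions, 0.51, was far below the 1.07 of regions overlapped by both replicates but 0.067 above the 0.44 of regions overlapped by 1 (permutation p = 1e-05 for each), whose score in the joint list may be lowered by the replicate that lacks them. Among regions of at least 1301 bp the excess over regions overlapped by 1 was only 0.02 (0.46 against 0.43, permutation p = 0.00092). How the replicate-set list was made stays open, and no biological explanation was tested.

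The single region of depletion in the replicate-set list lay on X at 16733265 to 16735119, over 1855 bp, with a score of -0.0095.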
